A study of Mus musculus with 3 samples.

How the data were processed

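The series holds ChIP-seq libraries from mouse liver: 1 for mTOR, 1 for ERRα and 1 rabbit IgG control. Per the labels' protocols, sonicated nuclei were clarified, complexes were isolated with the antibodies, and TruSeq libraries were sequenced as single 50-bp reads on a HiSeq instrument. Per the series design text, each ChIP library pooled 8 immunoprecipitations from the chromatin of 26 livers; the number behind the IgG library is not given in the sources used here. Groups were taken from the sample titles.

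The deposited values are signal tracks of tag coverage along the genome, which the authors scaled to 10000000 tags, per the file headers. The headers also give the totals of 62500000, 74200000 and 68800000 tags for mTOR, ERRα and IgG. The submitters' processing notes list BWA 0.5.9, MACS 1.4.1 and the build mm9, with no role for each. The program that wrote the tracks, the extension of tags and the treatment of duplicate reads are not given in the sources used here. From the values, coverage summed to 149 to 150 bp per tag in each track, so that tags appear to have been extended to about 150 bp; values were rounded to 0.1, and control coverage had not been subtracted. A bright repeat on chromosome 2 (98502289 to 98507590) held 3.54%, 3.24% and 3.76% of all coverage in the 3 libraries, so the scaling to total tags includes it.

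The tests planned before the data were examined assumed reads; the files held signal, so the planned procedure for signal was used, which gives no p-value. Coverage was averaged over 200-bp bins on chromosomes 1 to 19, X and Y, with positions in no interval counted as 0. A bin was called where the ChIP value plus 0.2 was at least 3 times the IgG value plus 0.2 and the ChIP value exceeded 2.01. The pseudocount of 0.2 was the 5th percentile, and 2.01 the 99.9th percentile, of IgG bins above 0, and adjacent bins were merged. The minimum level corresponds to about 16.7 tags per bin in the mTOR ChIP and 19.8 in the ERRα ChIP. The fold of a region is that of its highest bin. The roles of ChIP and IgG were swapped to count regions found without an antibody target. Overlap meant at least 1 bp, and was compared with 100 random placements of the mTOR regions over bins with IgG coverage, with independent lists over 12296738 bins, and with 5 simulated pairs of unchanged libraries drawn from the IgG levels and called against the same IgG library. Tags per bin were approximated from coverage, the library total and a tag length of 150 bp, and ratios were given exact binomial intervals without the pseudocount. Flanks were the bins 2 to 5 kb on both sides of the highest bin.

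The regions named in the text were chosen by a rule fixed before the data were examined for the case that genes could not be named: the 10 largest regions of each ChIP by fold, the 5 largest shared regions and the 5 most unequal regions in each direction. A shared region was ranked by the smaller of its ChIP folds in the highest mTOR bin. No mm9 annotation or sequence was used, and coordinates were not converted between builds. The planned distances to transcription start sites, promoter ratios, gene lists, cell type marker lists and motif searches were therefore not made. A table of genes on assembly GRCm38.p6 served only to count, per chromosome, transfer RNA genes and histone genes that neighbour another of their kind.

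The region caller was tested on simulated data for chromosome 19 (306712 bins) with 50 regions of 400 bp planted at each of several folds. At the mTOR depth 20% of regions planted at 3-fold, 86% at 5-fold and 100% at 10-fold and at 20-fold were recovered, with 2 false regions. At the ERRα depth the shares were 20%, 90%, 100% and 100%, with 0 false regions. Most regions planted at 3-fold were therefore missed at both depths under these settings. Chromosome M was left out of the comparisons. Alternatives were a minimum of 5-fold, other scalings, a doubled pseudocount of 0.4, the 99th percentile of IgG as the minimum level, no IgG, a longer overlap and the exclusion of bins above the IgG minimum level, together with 100-bp bins, merging across 200 bp and a local background, which were added after seeing the data. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures used Matplotlib 3.10.9.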

Results

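Binding of mTOR and of the estrogen-related receptor ERRα to chromatin was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in the livers of male C57Bl/6 mice aged 2 to 3 months. mTOR is the serine/threonine kinase that rapamycin inhibits through FKBP12, and ERRα is an orphan nuclear receptor known to regulate genes of mitochondrial energy metabolism. The series title places the experiment in a study of how the pathways of these proteins meet in fatty liver caused by rapamycin; no rapamycin-treated library was analysed here. There were 3 groups of 1 library each: the mTOR ChIP, the ERRα ChIP and a control made with rabbit immunoglobulin G (IgG). Each of the 2 ChIP libraries pooled 8 immunoprecipitations from the chromatin of 26 livers, so no value below has a replicate check, and each comparison is one of libraries. The headers of the tracks gave 62500000 tags for the mTOR ChIP, 74200000 for the ERRα ChIP and 68800000 for IgG. All values are coverage scaled by the authors to 10000000 tags, on which 1 tag was worth 0.16, 0.135 and 0.145 units respectively. Mean coverage of the autosomes was 0.626, 0.628 and 0.628, and tags covered 2.45, 2.45 and 2.46 Gb of the mouse genome (build mm9). Intervals of ratios are exact (Clopper-Pearson) 95% intervals on the approximate number of tags in a 200-bp bin; they cover counting error only, and how duplicate reads were treated is not given in the sources used here. Regions are given by position, because no mm9 gene annotation was used here.

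The first comparison asked where mTOR lay on liver chromatin above the IgG background. The mTOR ChIP exceeded IgG by at least 3-fold in 9069 regions that together spanned 3198 kb and held 1.13% of its coverage. The median width was 200 bp, a single bin and the smallest width that could be called. Most regions were modest: the median fold over IgG was 4.46, with quartiles of 3.54 and 6.31. A minority was far stronger, with 984 regions (10.9%) at 10-fold or more, 315 at 20-fold or more and 73 at 50-fold or more. The largest folds lay on chromosomes 9, 19 and 11. At chr9:82868801-82869800 coverage was 166 in the mTOR ChIP against 0.1 in IgG, a 552-fold excess whose interval ran from 272 to 60000 because the IgG value came from about 1 tag; it was 332-fold with the pseudocount doubled, 206-fold without IgG and 205-fold with a local background. The highest level of the 10 was at chr19:3767401-3768800, with 426 in the mTOR ChIP against 0.6 in IgG, which was 533-fold (interval 299 to 1775). At chr11:86570601-86571800 the values were 267 and 0.525, or 368-fold (209 to 1508). The remaining 7 of the 10 largest regions, at 109-fold to 287-fold, were chr5:137974001-137975000, chr2:116946001-116947000, chr14:51684201-51685200, chr11:29273201-29274400, chr1:84835801-84836600, chr1:167571401-167572800 and chr11:48669401-48670800. The lowest interval bound among the 10 was 65.4, and the width of their peaks at 50% of the maximum was 308 to 535 bp. In the same bins the ERRα ChIP was 0.5-fold to 10.9-fold over IgG, and its interval lay above 1 in 3 of the 10 regions. The clearest of these was chr1:84835801-84836600, where mTOR coverage was 106, ERRα coverage 7.60 and IgG 0.515, so that ERRα was also 10.9-fold over IgG (5.70 to 44.1). The 10 regions were chosen by mTOR fold over IgG, which favours low IgG values, and the ERRα intervals do not allow for this selection.

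With the roles of the libraries swapped, IgG exceeded the mTOR ChIP in 126 regions, equal to 1.39% of the mTOR count, and none of these reached 10-fold; unchanged libraries simulated at the mTOR depth gave a mean of 110.0 regions. The number of mTOR regions fell to 3787 at a minimum of 5-fold, and rose to 13877 with the minimum level lowered to the 99th percentile of IgG and to 15094 with a genome-wide mean in place of IgG. The swapped count ranged from 5 at 5-fold to 1678 with the lower minimum level. Because the minimum level was a percentile of IgG, it capped the IgG bins that could be called but not the ChIP bins. The swapped share of either ChIP therefore depends on that level and is not an error rate.

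**Figure D1:**
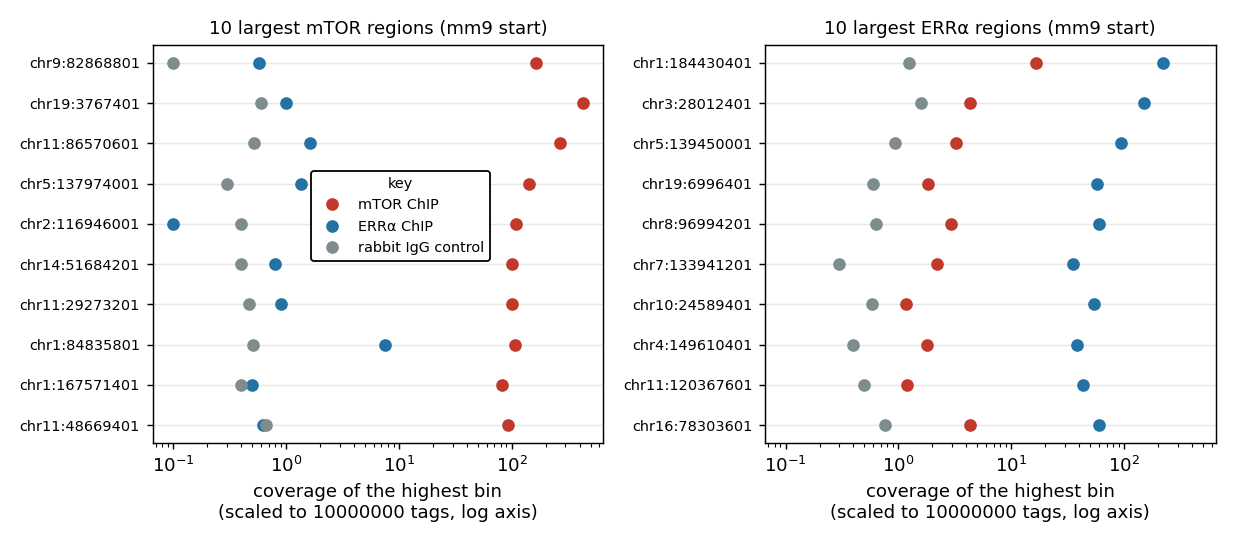
Coverage (scaled to 10000000 tags, log axis) of the mTOR ChIP (red), the ERRα ChIP (blue) and rabbit IgG (grey) in the highest 200-bp bin of the 10 largest mTOR regions (left) and the 10 largest ERRα regions (right), with mm9 start positions; each point is 1 library. In the left panel ERRα rises clearly above IgG at chr1:84835801 (7.60 against 0.515), and in the right panel mTOR is highest at chr1:184430401, at 16.5.

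The comparison of the ERRα ChIP with IgG was made in the same way. The ERRα ChIP exceeded IgG by at least 3-fold in 21764 regions spanning 8088 kb, with 2.36% of its coverage. Their median width was 400 bp, but widths came in steps of 200 bp. At the strongest 1000 regions of each ChIP, the median width at 50% of the maximum was 357 bp for ERRα and 327 bp for mTOR. The median fold of the ERRα regions was 4.26, with quartiles of 3.48 and 5.84. ERRα had more regions than mTOR and a smaller share of extreme ones: 1605 regions (7.37%) reached 10-fold, 269 reached 20-fold and 21 reached 50-fold, and the 99th percentile of the fold was 21.4 against 44.5 for mTOR. The largest was chr1:184430401-184431800, where coverage was 224 in the ERRα ChIP and 1.25 in IgG, or 154-fold (104 to 374). The mTOR ChIP reached 16.5 in the same bin, 11.5-fold over IgG (7.48 to 28.3). At chr3:28012401-28013600 ERRα coverage was 149 against 1.59 in IgG, which was 83.4-fold (55.1 to 163), and 185-fold without IgG. At chr5:139450001-139451800 it was 94.6 against 0.941, or 83.1-fold (50.5 to 211). The remaining 7 of the 10 largest, at 62.4-fold to 72.7-fold, were chr19:6996401-6997400, chr8:96994201-96995000, chr7:133941201-133942400, chr10:24589401-24590200, chr4:149610401-149611400, chr11:120367601-120368600 and chr16:78303601-78304600. Outside the chromosome 1 region, the mTOR ChIP was 1.75-fold to 4.79-fold over IgG at the other 9 regions, and over all 10 its interval lay above 1 in 8. At chr16:78303601-78304600, for example, mTOR coverage was 4.28 against 0.761 in IgG (4.66-fold, 2.49 to 15.1), and at chr10:24589401-24590200 it was 1.17 against 0.582 (1.75-fold, 0.686 to 8.21). The 10 regions were chosen by ERRα fold over IgG, which favours low IgG values. The mTOR intervals use the same IgG values and do not allow for this selection.

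Both sets were densest on the same gene-rich chromosomes. Chromosome 19 held 6.12 mTOR regions per Mb of covered sequence and chromosome 11 held 5.76, against a median of 3.85 over the 19 autosomes and a minimum of 2.57 on chromosome 3. ERRα regions reached 15.1 per Mb on chromosome 11 and 14.1 on chromosome 19, with a median of 9.68 and a minimum of 6.02, again on chromosome 3. Chromosome X held 53 mTOR regions (0.375 per Mb) and 134 ERRα regions (0.948 per Mb), at a mean coverage of 0.435 and 0.432 times that of the autosomes in these male livers. Chromosome Y held 2 mTOR regions and no ERRα region. IgG exceeded the ERRα ChIP in 116 regions, equal to 0.533% of the ERRα count, of which 1 reached 10-fold, and simulated unchanged libraries gave a mean of 47.4. The ERRα count fell to 8272 at a minimum of 5-fold and rose to 32847 with a genome-wide mean in place of IgG, while the swapped count ranged from 4 to 1475.

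**Figure D2:**
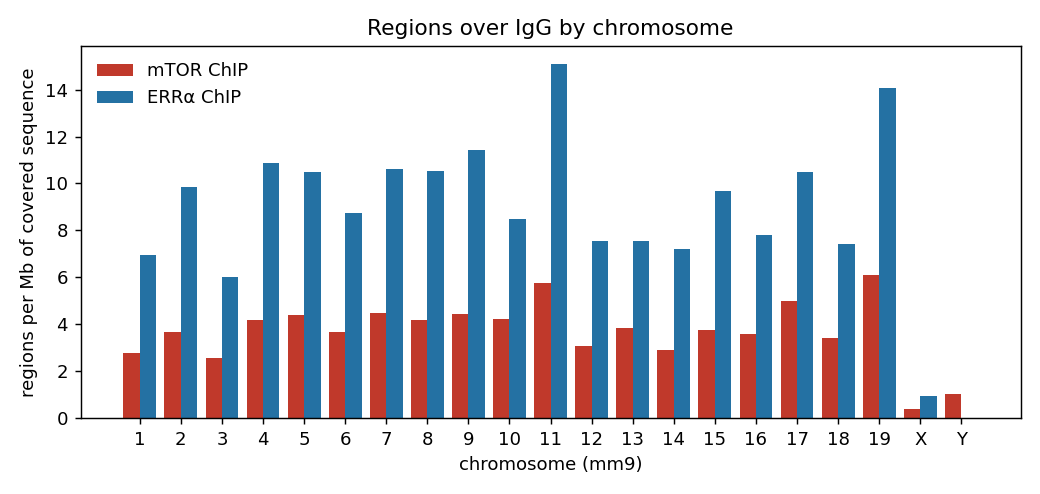
Regions at least 3-fold over IgG per Mb of covered sequence (bars, from 0) for the mTOR ChIP (red) and the ERRα ChIP (blue), 1 library each, on each mm9 chromosome. Chromosomes 11 and 19 stand highest in both, up to 6.12 per Mb for mTOR and 15.1 for ERRα, and chromosome X, with lower mean coverage but the same minimum level, lies below 1 per Mb in both.

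The next comparison asked whether mTOR and ERRα occupied the same sites. Most regions belonged to a single ChIP: 8523 mTOR regions did not touch an ERRα region, and 21225 ERRα regions did not touch an mTOR region. The shared set held 546 mTOR regions, or 6.02% of them (exact binomial 95% interval 5.54 to 6.53), and 539 ERRα regions (2.48%). That interval treats the called regions as independent draws. It covers neither a repeat of the libraries nor the choice of settings. Among the strongest regions the overlap went in unequal ways: 169 of the 1605 ERRα regions at 10-fold or more were shared (10.5%), against 55 of the 984 such mTOR regions (5.59%). The shared region with the largest smaller fold was chr2:132403801-132404600, where mTOR coverage was 58.5, ERRα coverage 19.1 and IgG 0.596, so that mTOR was 73.8-fold (45.7 to 332) and ERRα 24.2-fold (14.7 to 109) over IgG. At chr1:184430801-184431400, inside the largest ERRα region, mTOR was 17.8-fold (11.3 to 53.5) and ERRα 193-fold (125 to 574) over IgG. The other shared regions of this rank were chr9:123438201-123439000, chr5:125889001-125890200 and chr18:12713601-12714400. At chr9:123438201-123439000 coverage was 24.3 in the mTOR ChIP and 16.5 in the ERRα ChIP, with a ratio of 1.47 (1.20 to 1.83). mTOR coverage was also the higher at chr5:125889001-125890200 (42.2 against 10.3) and at chr18:12713601-12714400 (11.4 against 6.29).

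The same mTOR regions placed at random on their chromosomes met ERRα regions 46.6 times on average and at most 62 times in 100 placements, so the observed overlap was 11.7 times the random one. Counted in bins, 728 were called in both ChIPs against 52.6 for independent lists, and unchanged libraries simulated against the same IgG library shared 0 regions, but with means of 110.0 and 47.4 regions these lists were too short for that value to bear on lists of the observed length. Neither the random placements nor the independent lists were matched on coverage level or open chromatin. A preference of both ChIPs for such sequence could therefore give part of the excess. Part may also come from the IgG library, which served both comparisons and could not be split. The shared count was 90 at a minimum of 5-fold, 1003 with the lower minimum level, 339 with the pseudocount doubled, 308 with a local background and 852 with 100-bp bins, the last 2 added after seeing the data. With a genome-wide mean in place of IgG it was 2973. That setting kept bins with IgG above 2.01, so sequences with high coverage in all libraries could enter both lists.

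The coverage of each ChIP was also taken at the regions of the other. At the strongest 1000 ERRα regions the median ratio of the highest bin to flanks 2 to 5 kb away was 16.3 in the ERRα ChIP, 1.62 in the mTOR ChIP (quartiles 1.13 and 2.31) and 0.869 in IgG. At the strongest 1000 mTOR regions it was 15.5 in the mTOR ChIP, 0.985 in the ERRα ChIP (0.638 and 1.47) and 0.817 in IgG. Random bins gave 0.934, 0.925 and 0.947 for mTOR, ERRα and IgG. Because regions chosen for a high ratio over IgG favour bins with low IgG, the same ratios were taken at the strongest 1000 regions called without IgG. These were called over the genome-wide mean of each ChIP, from 12992 mTOR and 30839 ERRα regions. Bins with IgG above 2.01 were left out, so high IgG stayed excluded by selection. mTOR then stood at 1.77 (1.27 and 2.43) at ERRα regions, where IgG was 1.19 and the summed mTOR excess over flanks equalled 5.37% of the ERRα excess. ERRα stood at 1.13 at mTOR regions, where IgG was 1.08 and the summed ERRα excess equalled 3.46% of the mTOR excess. Over all regions called without IgG these shares were 10.2% and 18.2%: mTOR stood at 1.31 (0.966 and 1.77) at ERRα regions, where IgG was 1.22, and ERRα at 1.23 (0.825 and 1.87) at mTOR regions, where IgG was 1.17. With these regions split into 5 equal groups by level, ERRα stood at 1.41 and 1.38 in the 2 lowest groups of mTOR regions, where IgG was 1.32 and 1.25, and mTOR at 1.29 and 1.29 in the 2 lowest groups of ERRα regions, where IgG was 1.28 and 1.24. In the highest group ERRα stood at 1.08 at mTOR regions, where IgG was 1.07, and mTOR at 1.44 at ERRα regions, where IgG was 1.18.

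**Figure D3:**
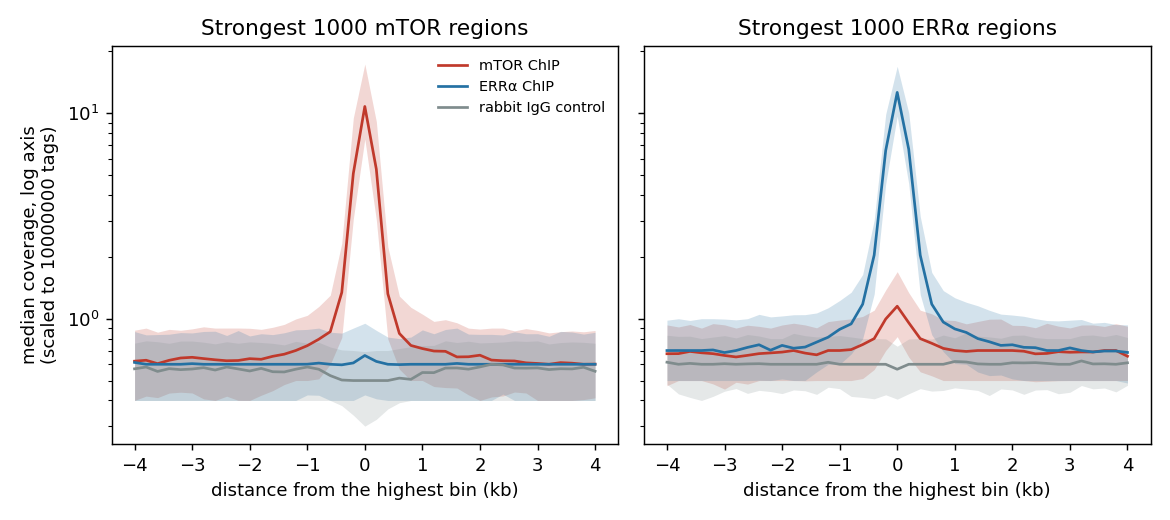
Median coverage (lines, log axis, scaled to 10000000 tags) with quartiles (shading) in 200-bp bins up to 4 kb on each side of the highest bin, at the strongest 1000 mTOR regions (left) and the strongest 1000 ERRα regions (right), for the mTOR ChIP (red), the ERRα ChIP (blue) and rabbit IgG (grey), 1 library each. A low mTOR peak stands at the ERRα regions, with a median ratio to the flanks of 1.62, while ERRα stays near its flanks at the mTOR regions, at 0.985.

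The ChIPs were also compared with each other directly, without IgG in the ratio, at the 30159 regions found for either. mTOR was the higher in 8590 (28.5%) and ERRα in 21568. mTOR exceeded ERRα by at least 3-fold in 6103 regions (20.2%), ERRα exceeded mTOR by at least 3-fold in 14125 (46.8%), and 9931 (32.9%) lay within 3-fold. The counting interval of the ratio lay above 1 in 7850 regions, below 1 in 19721, and included 1 in 2588, where no difference was detectable at this depth. Regions entered because a ChIP was high there, and the bin compared was the one with the highest value of either ChIP. The intervals do not allow for this selection, which favours unequal values, so these counts do not measure how many regions differ. The most unequal region in favour of mTOR was chr2:116946001-116947000, at 108 against 0.1 (362-fold, 192 to 42340, with about 1 ERRα tag), followed by chr19:3767401-3768800 at 352-fold (229 to 879), chr9:82868801-82869800 at 214-fold, chr11:86570601-86571800 at 145-fold and chr14:51710001-51710800 at 124-fold. In favour of ERRα the ratios were smaller, led by chr10:42182401-42183600, where ERRα coverage was 56.9, mTOR 1.10 and IgG 1.25, so that ERRα was 44.1-fold above mTOR. The next were chr10:24589401-24590200 (39.5-fold), chr14:105697401-105698800 (39.1-fold), chr5:64687801-64688800 (37.6-fold) and chr6:67057401-67058600 (36.1-fold). In all 5 of these regions the counting interval of mTOR over IgG included 1, and mTOR coverage was 0.4 to 1.17. The share of regions with mTOR higher depends on how many regions each ChIP contributed.

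**Figure D4:**
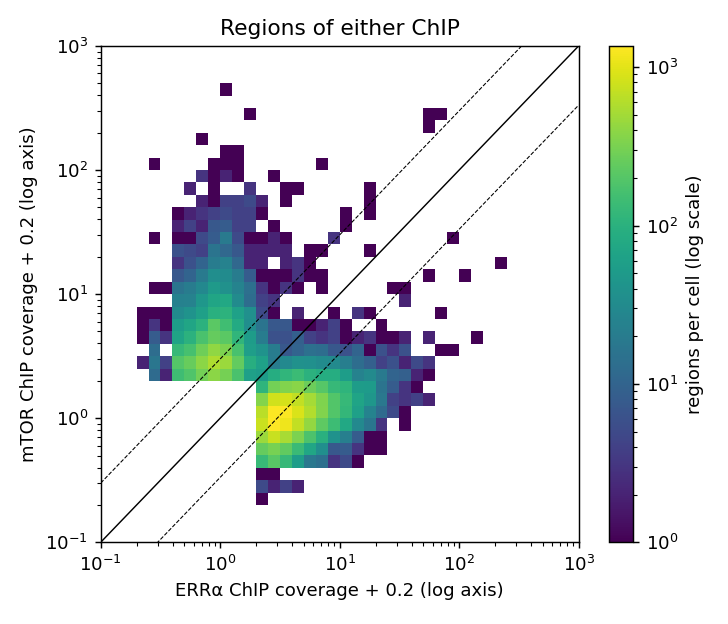
Number of regions of either ChIP (colour, log scale) by ERRα coverage (horizontal) and mTOR coverage (vertical) in the highest bin, both plus a pseudocount of 0.2 on log axes, 1 library each; the solid line marks equal values and the dashed lines a 3-fold difference. Of 30159 regions, 6103 lie at or above the upper dashed line and 14125 at or below the lower one, and the empty corner is set by the minimum level.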

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

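The width of the mitochondrial mTOR peak was tested by a rule set before that width was seen; the tests of its height and of its shoulders were chosen after the results were seen.

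The mitochondrial chromosome, which the comparisons left out, carried signal above IgG. Mean coverage of its covered positions was 358 (357.7) in the mTOR ChIP against 119 in the ERRα ChIP and 120 in IgG, so that mTOR was at 2.97 times and ERRα at 0.988 times IgG. No interval was computed for these ratios, and 4076 positions had no IgG coverage, the longest stretch being chrM:6542-9683. The ERRα ChIP was highest relative to IgG at chrM:2601-2800, with 322.5 against 104.7 (3.08 times), while over the other covered bins the median ERRα ratio was 0.885. At chrM:2601-2800 the mTOR ChIP was at 2.50 times IgG, close to its median of 2.48 over other covered bins.

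In the mTOR ChIP a sharp peak stood near the end of the linear mitochondrial sequence: the fully covered bin chrM:16001-16200 held 2239 against 146 in IgG and 134 in the ERRα ChIP, 15.4 times IgG, and the maximum of 2917 lay at position 16152. A larger amount of mitochondrial DNA in the mTOR library would raise all bins alike, but the 56 other covered bins had a median ratio of 2.48 (5th to 95th percentile 2.00 to 3.54), which argues against it for the peak at 15.4 (15.35) and leaves it open for the rise elsewhere. The width of the central part at 50% of the maximum was 195 bp, close to the tag length of about 150 bp. It lay below the median of 327 bp at the strongest 1000 nuclear mTOR regions. However, this width was taken on mTOR coverage not divided by IgG, and IgG also fell beside the peak bin. IgG was 146 in that bin, 50.2 at chrM:15801-16000 and 92.7 at chrM:1-200. The width can therefore not decide whether duplicate tags piled at a single position gave the central part, which stays open. Tags piled at the maximum would not reach the preceding bin chrM:15801-16000, where mTOR was still 8.02 (8.024) times IgG, so a single pile does not account for that shoulder, while piles at several positions stay open; the bins after the peak, which were not fully covered, were at 16.6 times IgG up to the end of the sequence and at 11.1 times at chrM:1-200. No biological explanation was tested, since no group of the design bears on the mitochondrial chromosome.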

How the results depend on the processing

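The alternatives marked "added" were chosen after seeing the data. Scaling by 10-kb bins or by the median bin, merging across 200 bp, an overlap of at least 50% of the shorter region and leaving out bins above the IgG minimum level kept the region counts that they gave within 1.5 times, and ERRα had more regions than mTOR in all settings. At least 5-fold left 3787 mTOR, 8272 ERRα and 90 shared regions, 5 and 4 swapped regions over mTOR and over ERRα, and mTOR higher in 31.1%; fewer bins pass by construction. The 99th percentile of IgG as the minimum level, which admits more bins, gave 13877 mTOR, 1003 shared and 1678 and 1475 swapped regions, with mTOR higher in 32.8%. A genome-wide mean without IgG, which here kept bins with high IgG, gave 15094 mTOR, 32847 ERRα and 2973 shared regions and 29.7%. Doubling the pseudocount gave 339 shared and 37 and 26 swapped regions. Scaling by the median bin gave 29.2%. The added 100-bp bins gave 852 shared and 683 and 687 swapped regions and 30.2%, and the added local background 308 shared regions and 27.7%. Except where the construction shows it, the cause was not tested. The counting intervals of the 20 largest regions were wide. Their IgG values came from about 1 to 6 tags at the mTOR regions and 3 to 15 at the ERRα regions. The scalings multiplied ChIP coverage by only 1.03 to 1.07. Staying inside an interval therefore does not show that a fold is stable. Of 120 recomputed folds of these regions, 117 stayed inside their counting intervals and the lowest was 38.3. Outside lay the largest mTOR region, chr9:82868801-82869800, which fell from 552-fold to 206-fold without IgG and to 205-fold with the local background, and chr3:28012401-28013600, which rose from 83.4-fold to 185-fold for ERRα without IgG. By construction only the background value changed there, from an IgG value of 0.1 at the chromosome 9 region and 1.59 at the chromosome 3 region. chr19:3767401-3768800 was above the chromosome 9 region with the pseudocount doubled (426 against 332), without IgG (529 against 206), with the local background (462 against 205) and with 100-bp bins (660 against 639). The swapped counts have no value without IgG, with the local background or with high IgG bins left out. Not run, for lack of reads or of an mm9 annotation: stricter p-values, duplicate handling, read extension, random parts of the IgG reads, and all alternatives for start sites, promoters, gene lists and motifs. At this depth the counting interval of mTOR over ERRα included 1 in 2588 of 30159 regions, without allowance for the selection of regions and bins by the same values.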

Other observations

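All tests in this part were chosen after the results were seen.

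A block on chromosome 17 stood out among sequences with high coverage in all libraries. In chr17:39979801-39985800, coverage averaged 170 (169.8) in the mTOR ChIP against 48.1 in the ERRα ChIP and 53.3 in IgG, so that mTOR was at 3.19 times and ERRα at 0.903 times IgG. Each of its 30 bins had mTOR above IgG, from 2.41 to 4.10 times. The other 78 blocks of at least 3 bins with IgG above 10 had mTOR at 0.711 to 1.13 times IgG, with a median of 0.939, among them the bright repeat on chromosome 2. The ERRα ratio was highest in a different block, chr18:3004401-3006400, at 1.85 times IgG, where mTOR was at 1.00. The block on chromosome 17 contributed 3 of the mTOR regions counted above, and it was singled out after its values were seen.

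The strongest mTOR regions lay close together. Of the 300 mTOR regions with the largest fold, 63 (21.0%) fell in 13 clusters of at least 3 regions with gaps of at most 100 kb, against a mean of 1.73 and a maximum of 12 in 1000 random draws of 300 from all mTOR regions. Of the 300 strongest ERRα regions, 4 did so, in 1 cluster, and random draws reached 10. The largest mTOR cluster, chr13:23528001-23622600, held 10 regions with median coverage of 32.7 in the mTOR ChIP, 0.811 in the ERRα ChIP and 0.573 in IgG. Further clusters lay at chr1:172963601-173042000, chr13:21252401-21371800 and chr6:128709801-128793600, with 6 regions each. The mTOR count stayed between 59 and 64 in the settings that use IgG. With a genome-wide mean in place of IgG it was 89, and the ERRα count rose from 4 to 57. That setting kept bins with high IgG, so sequences with high coverage in all libraries could enter the strongest 300.

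A candidate explanation for the clusters is binding of mTOR, or recovery of DNA by its antibody, at groups of transfer RNA (tRNA) genes, which are transcribed by RNA polymerase III. A local gain of copies or of mapped reads would raise IgG as well, so choosing by fold over IgG already left out such gains. The ERRα values at these regions can therefore not test that explanation. The median ratio of the highest bin to its flanks at the 63 regions was 1.08 (1.082) in the ERRα ChIP, with quartiles of 0.795 and 1.46. In the mTOR ChIP it was 19.9. Groups of histone genes cannot be the whole source, since 33 of the 63 regions lay on chromosomes without neighbouring histone genes, although on chromosome 13, with 21 clustered regions, both 103 neighbouring tRNA genes and 54 neighbouring histone genes (assembly GRCm38.p6) leave them open. Over 20 chromosomes, the number of neighbouring tRNA genes rose with that of clustered mTOR regions, with Pearson's r = 0.922 (permutation p = 5e-05, adjusted 0.0002) and Spearman's rho = 0.733 (permutation p = 0.00043, adjusted 0.00172, 4 relations, two-sided), and without chromosomes 13 and 6 r was 0.661 and rho 0.620. The relation is a hypothesis about chromosomes and not about sites, and chromosome 3 had 31 such tRNA genes and 0 clustered regions.

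For the other relations computed, neighbouring tRNA genes had r = -0.109 (permutation p = 0.699) and rho = -0.101 (p = 0.8) with clustered ERRα regions, and r = 0.10 (p = 0.662) and rho = 0.150 (p = 0.525) with all mTOR regions; without chromosomes 13 and 6 r was -0.104 and 0.193. Neighbouring histone genes had r = 0.791 (permutation p = 0.0245, adjusted 0.049) and rho = 0.349 (p = 0.213, adjusted 0.426) with clustered mTOR regions, and without chromosomes 13 and 3 r was 0.529.

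The low mTOR peak at ERRα regions, 1.31 times its flanks over all regions called without IgG and 1.77 times at the strongest 1000, could come from carry-over of ERRα DNA, from open chromatin that any antibody recovers, from both, or from mTOR at these sites. These regions left out bins with IgG above 2.01, and the effect of this on the comparisons below was not tested. Carry-over as the whole source would make the mTOR excess 1 share of the ERRα excess, but this share was 19.3% (19.29%, bootstrap 95% interval over regions 18.2 to 20.6) in the lowest and 6.58% (6.03 to 7.32) in the highest of 5 equal groups by ERRα level. At the strongest 1000, the dispersion of mTOR tags around 1 share was 19.8 times that of IgG around its flanks (2.32 times without the 1% most deviant regions). Over all regions it was 5.01 times, but 1.45 times without the most deviant. The latter is below the 1.5 times that the rule for the strongest 1000 asked for, so the dispersion over all regions does not decide. Open chromatin as the whole source would keep mTOR at 1 multiple of IgG, but the mTOR excess was 1.29 (1.21 to 1.36) times the IgG excess in the lowest and 3.14 (2.86 to 3.54) times in the highest group; without the 1% most deviant regions the groups also lay apart, at 17.0% and 5.64% for the share and 1.16 and 2.65 for the multiple. Both together stay open: with the IgG excess subtracted, the mTOR share was 4.29% (4.294%, 3.22 to 5.43) in the lowest and 4.48% (3.96 to 5.24) in the highest group, as 1 share would give, but 2.39% (1.76 to 3.13) and 3.51% (3.31 to 3.70) without the 1% most deviant regions. Binding of mTOR, and recovery of open chromatin by the mTOR antibody alone, were not tested.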
